A study of Homo sapiens with 24 samples.

How the data were processed

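The series measured cytoplasmic RNA by sequencing in 24 libraries of U2OS cells, in 4 siRNA series of 6 times of actinomycin D, with 1 library for each series and time. Per the labels' protocols, cytoplasmic RNA was taken with a column kit after lipid transfection of the siRNAs, and standard Illumina libraries were made. Reads were aligned by the authors to the human genome build hg19 with TopHat 1.3.3, per the submitters' processing notes. The authors deposited 1 table of FPKM values (fragments scaled to the length of the transcript and to the mapped reads of the library), with 1 row for each RefSeq transcript. The tool that made the FPKM values, its version and the annotation release are not given in the sources used here. FPKM divide by the length of a transcript and by the reads of a library, so they show relative levels, and reads that fit several transcripts or gene copies may have been split or dropped. Read totals cannot be recovered from these values, so the depth is unknown and no counting error is given.

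The table held 37382 transcripts of 22925 gene symbols. The 154 transcripts without a symbol held 0.014% of the FPKM and were left out. A dash stood in place of a value in 3766 cells of 834 transcripts and was read as missing. The FPKM of a gene is the sum over its transcripts. Some abundant genes were listed at 0 in single libraries between high values, which is read here as a failed estimate. Of 9890 genes with a mean of at least 1 FPKM, 456 with a dash were therefore left out, and 1574 with a 0 next in time to a value of at least 1 FPKM in the same series. That rule for zeros was made after the values had been seen. The remaining 7860 genes were tested, of which 134 hold a 0. A gene listed at 0 in all 6 libraries of a series passes that rule. Values were taken as log2(FPKM + 0.1), and the median of the tested genes was subtracted from each library. No spike-in RNA is named in the labels, so a slope shows loss relative to the median value of each library and not an absolute half-life. Fold changes are on the log2(FPKM + 0.1) scale and understate the changes of low genes; no fold is given against a series listed at 0.

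Slopes were compared in limma 3.58.1 (R 4.3.3) with a model of time as a factor, series, and series by time in hours, fitted to all 24 libraries with a mean-variance trend. Levels were compared with time as a factor and series. The decay in the control series came from a straight line for each series. With no repeated time point, the spread is the scatter of the time points about these courses. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of each comparison. The lists covered immediate-early genes, zinc-finger genes, ribosomal proteins, oxidative phosphorylation, glycolysis, replication-dependent histones, mitochondrially encoded genes, nuclear-retained RNAs, mRNA decay, the microRNA machinery, let-7 targets, targets of nonsense-mediated decay, interferon response, p53 targets, cholesterol synthesis, the unfolded protein response, G2 and M phase, S phase, extracellular matrix and markers of other cell types. PAN3 was compared by an exact sign-flip test over the 6 times. The spread of slopes was compared by exchanging 2 series at every subset of times, which gives 32 distinct swaps. Correlations between comparisons that share the control libraries were set beside 20 simulated sets of unchanged series.

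The genes named were fixed by a rule: in each comparison, the 10 largest differences in each direction among called genes whose difference kept its sign when any time was left out; for the control decay, the 10 most negative and 5 most positive slopes; PAN3 and PAN2; and up to 4 members of each list described, by smallest p. Some genes that this rule names are not reported here. Where no gene was called, the 5 smallest unadjusted p in each direction are named. PPIA, RPL3 and TUBB, and the genes of the unfolded protein response whose levels are given, were named after their values had been seen.

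The comparisons were tested on simulated data made from the mean at each time and the residual SD of the 7860 genes, with 100 genes changed at each size. In the long-labelled, short-labelled and both-labelled comparisons, slope changes of 0.1 log2 units per h were recovered in 11, 14 and 19 cases and those of 0.2 in 39, 40 and 49, with 5, 1 and 1 false calls. Level changes of 0.5 were recovered in 54, 51 and 43 cases and those of 1 in 79, 80 and 84, with 7, 5 and 7 false calls. Alternatives were fixed in advance: pseudocounts of 1 and 0.01, filters at 0.1 and 5 FPKM or none, uncentred and quantile-normalised values, no trend, straight lines, only the 12 libraries compared, 0 to 4 h only, and leaving out each time and each library. Others were added after the data had been seen: zeros kept, genes with any 0 left out, transcripts in place of genes, slope variance less its error, genes with certain heptamers left out, 0 to 2 h only, and PAN3 without the time at which the control lists it at 0.

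For 3' UTR sequence, the longest annotated 3' UTR of at least 50 bases was taken for each gene from GENCODE release 29 (build GRCh38), with older symbols matched through a symbol table; 6967 of the 7860 genes (88.6%) had one. Level and slope differences, limited to 3 log2 units and 0.5 log2 units per h, were regressed on the presence of each of 14591 heptamers found in at least 100 genes, with 3' UTR length and GC content in the regression. The t of a heptamer is a description of these libraries, given with its rank and the largest absolute t in 100 shuffles of the genes. In simulated data a shift of -0.5 ranked its heptamer lowest in 20 of 20 draws and a shift of -0.2 in 16 of 20. Scripts ran under Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.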

Results

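Cytoplasmic RNA of U2OS cells, a human osteosarcoma line, was sequenced in 24 libraries. The cells had been transfected with a control siRNA, with an siRNA labelled as directed against the long isoform of PAN3, with another labelled for the short isoform, or with both, and were sampled 0, 0.5, 1, 2, 4 and 6 h into treatment with actinomycin D, which blocks transcription. PAN3 is the adaptor of the PAN2-PAN3 deadenylase, which shortens the poly(A) tails of mRNA. The design addresses how the loss of either PAN3 isoform alters mRNA turnover. Each siRNA and time had 1 library, so each of the 4 series held 6 libraries and no time point was repeated. Because no test found PAN3 itself lower in the libraries labelled as knockdowns, these are called the long-labelled, short-labelled and both-labelled series throughout, and each direction given for them rests on those labels.

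The deposited FPKM values summed to between 324072.2 and 384287.0 per library, with 8973 to 9704 genes at 1 FPKM or more. The 10 most abundant genes held 5.56% to 7.83% of the FPKM. Read totals were not part of the table, so the depth behind single values is unknown. Between 0 and 6 h the median log2 value of the 7860 genes tested moved from 3.725 to 3.401 in the control series, from 3.652 to 3.394 in the long-labelled, from 3.604 to 3.325 in the short-labelled and from 3.626 to 3.378 in the both-labelled series. Slopes are therefore given relative to the median value of the tested genes in each library, called the median gene below. They are in log2 units per h with their standard error (SE). A positive slope marks an RNA lost more slowly than the median, or one whose FPKM rose. The FPKM of a gene is its mean over the 6 libraries of a series. The p-values measure the scatter of the time points about a fitted course within series that may each stem from a single transfection.

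PAN3 was listed at low values in all series. In the control libraries it stood at 1.16 FPKM at 0 h, 1.33 at 0.5 h, 0.64 at 1 h, 0.4 at 2 h, 2.4 at 4 h and 0 at 6 h. The long-labelled libraries held 0.45, 1.19, 0.38, 0.43, 1.7 and 1.25 FPKM at the same times, and the short-labelled libraries 1.76, 1.84, 1.76, 2.97, 4.01 and 2.72. The both-labelled libraries held 1.66, 0.41, 0.71, 2.49, 1.72 and 1.7. The mean was 0.988 ± 0.847 FPKM in the control and 0.898 ± 0.556 in the long-labelled series (SD, n = 6 each; exact sign-flip p = 0.812, two-sided). In the short-labelled series PAN3 averaged 2.51 ± 0.901 and was higher than the control at 6 of 6 times (exact p = 0.031, the smallest that 6 pairs can give; adjusted over the 3 series, 0.0936). The both-labelled series averaged 1.45 ± 0.759 (exact p = 0.406). The control value of 0 at 6 h follows 2.4 FPKM and by the rule used for other genes would be a failed estimate. Without that time the control averaged 1.19 FPKM. The long-labelled series then differed from it by -0.359 (lower at 4 of 5 times, exact p = 0.125), the short-labelled by 1.28 (higher at 5 of 5, exact p = 0.0625) and the both-labelled by 0.214 (exact p = 0.812), where 0.0625 is the smallest p that 5 pairs can give. The table holds a single PAN3 transcript, which does not separate the isoforms. PAN2, the catalytic partner, was listed at 8.5 to 11.94 FPKM in the control series. It was listed at 0 in the long-labelled library of 0 h and at 7.46 to 9.1 FPKM in the others of that series. PAN2 was listed at 0 in the short-labelled libraries except for 6.12 FPKM at 0.5 h, and in the both-labelled libraries except for 5.83 FPKM at 1 h. Such zeros can be failed estimates, since PPIA, RPL3 and TUBB, which most cells transcribe strongly, were also listed at 0 in some or all libraries.

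**Figure D1:**
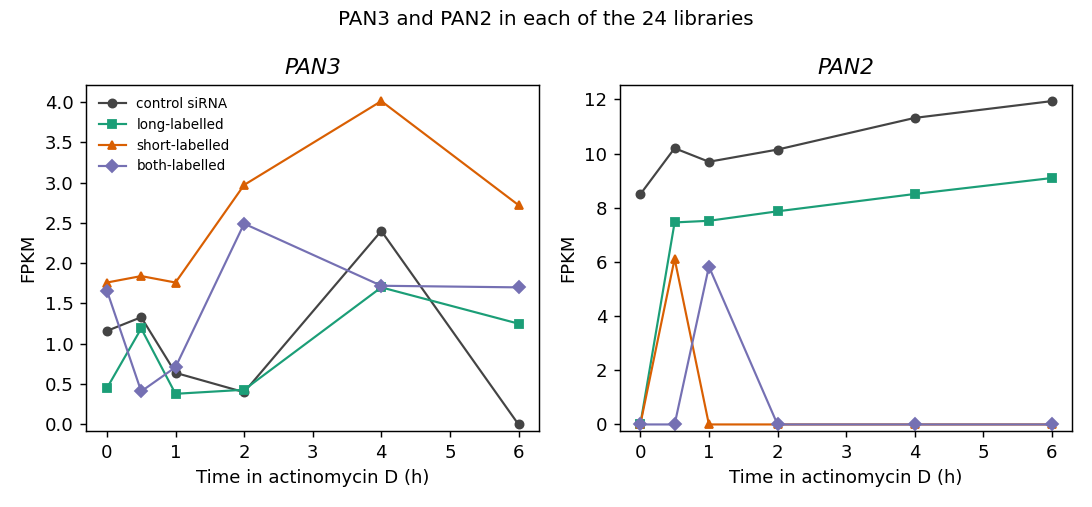
FPKM of PAN3 (left) and PAN2 (right) against hours in actinomycin D, 1 point per library and 1 line per series. PAN3 in the short-labelled series lies above the control at 6 of 6 times, and PAN2 is listed at 0 in most short-labelled and both-labelled libraries.

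The control series gives the baseline of mRNA loss. Transcripts lost fastest relative to the median gene encoded regulators. ZNF828, a zinc-finger protein, had a slope of -1.07 ± 0.10 log2 units per h and the homeobox gene HHEX -0.81 ± 0.07. The transcriptional regulators CITED2 and CITED4 had slopes of -0.73 ± 0.12 and -0.72 ± 0.03 and the transcription factor GATA6 -0.74 ± 0.18. CSRNP1, NUAK2, ZNF322 and CHAC1 were also among the 10 most negative slopes, at -0.89, -0.76, -0.73 and -0.72. The most positive slopes belonged to RIF1 (0.79 ± 0.16), the small Cajal body RNAs SCARNA9 (0.77 ± 0.11) and SCARNA17 (0.67 ± 0.10), MTRNR2L2 (0.66 ± 0.16), a nuclear copy of mitochondrial rRNA sequence whose reads the mitochondrial genome could share, and the syndecan gene SDC3 (0.63 ± 0.11). With limma, 3683 of 7860 genes had a control slope different from 0 at an adjusted p under 0.05, with 2368 above 0 and 1315 below. Here 0 is the course of the library median and not the middle of the slopes, as the median control slope was 0.0441. The split is therefore shifted towards slower loss and depends on the centring. Without centring the FPKM, the split was 1103 and 1939. Over the times 0 to 2 h alone the count was 1107.

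Among lists fixed before the data were examined, immediate-early genes, which growth signals switch on within minutes, were lost fast in the control series. Of these, 28 of 47 fell faster than the median gene and 1, PLAUR, more slowly (adjusted over the list alone, 34 and 1). These counts and those of the next lists are of slopes against 0, so they carry the same shift. Camera compares a list with the other genes. RND3 had a slope of -0.55 ± 0.07, SERTAD1 of -0.71 ± 0.09 and DUSP4 of -0.50 ± 0.08. The camera test gave an adjusted p of 6.04e-09, and an adjusted p = 0.416 with an estimated correlation. Zinc-finger genes, mostly transcription factors, had 36 of 102 members faster and 2 slower (adjusted over the list alone, 34 and 2). Camera gave them an adjusted p = 7.25e-07, and an adjusted p = 0.265 with an estimated correlation. Members lost faster included ZNF828 (-1.07 ± 0.10), ZNF622 (-0.43 ± 0.03), ZNF330 (-0.45 ± 0.03) and ZNF672 (-0.35 ± 0.05). p53 targets had 9 of 25 members faster and 4 slower (adjusted over the list alone, 10 and 4; camera adjusted p = 0.0253, and adjusted p = 0.265 with an estimated correlation), among them CDKN1A (-0.21 ± 0.01) and SESN2 (-0.46 ± 0.08). Nuclear genes of oxidative phosphorylation were lost slowly, with 45 of 67 slower and 0 faster (adjusted over the list alone, 46 and 0; camera adjusted p = 2.25e-07, and adjusted p = 0.416 with an estimated correlation), as ATP5B at 0.13 ± 0.01 and NDUFB5 at 0.13 ± 0.02. Of the ribosomal protein genes 41 of 64 were slower and 0 faster (adjusted over the list alone, 46 and 0; camera adjusted p = 7.87e-06, and adjusted p = 0.416 with an estimated correlation), including RPL41 (0.14 ± 0.02) and RPS15 (0.19 ± 0.03); many have near-identical processed pseudogenes whose reads may be shared. Extracellular matrix genes had 9 of 18 members slower and 0 faster (adjusted over the list alone, 10 and 0; camera adjusted p = 0.0253, and adjusted p = 0.265 with an estimated correlation), with COL4A1 at 0.14 ± 0.02.

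In the long-labelled series, 7 of 47 immediate-early mRNAs were lost more slowly than in the control and 1 faster. MYC, a growth-promoting transcription factor, went from 128.36 to 8.29 FPKM between 0 and 6 h in the control series and from 180.12 to 31.1 FPKM in the long-labelled series, a slope difference of 0.23 ± 0.05 log2 units per h (limma adjusted p = 0.0234). That call was lost without the libraries of any single time other than 2 h, with an adjusted p of 0.066 without 0 h, 0.084 without 0.5 h, 0.0725 without 1 h, 0.0728 without 4 h and 0.185 without 6 h. The small GTPase gene RHOB (0.22 ± 0.03), the phosphatase gene DUSP4 (0.18 ± 0.03) and the differentiation inhibitor ID3 (0.26 ± 0.05) were also lost more slowly. Adjusted over the list alone, 10 had a higher and 1 a lower slope, and the median difference of the list was 0.075. The list passed camera (adjusted p = 3.47e-06) but not with an estimated correlation (adjusted p = 0.0753).

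Over all genes, 144 slopes differed between the long-labelled and control series, 98 higher and 46 lower. The higher slopes were led by ZNF828 (0.61 ± 0.14), HHEX (0.53 ± 0.10), SURF6 (0.44 ± 0.07), a nucleolar protein gene, CITED4 (0.43 ± 0.04), UFSP1 (0.40 ± 0.10), C7orf25 (0.38 ± 0.08), KIAA0907 (0.33 ± 0.07), the haem oxygenase gene HMOX1 (0.32 ± 0.07), IRF2BP2 (0.31 ± 0.05) and SLAIN2 (0.31 ± 0.06). CITED4 had the smallest adjusted p, 0.000108 with limma. Lower slopes were found for EXOSC4, a subunit of the RNA exosome (-0.50 ± 0.07), the cell-cycle genes PKMYT1 (-0.40 ± 0.09) and MYBL2 (-0.35 ± 0.06), the ribosomal protein gene RPL36 (-0.40 ± 0.09), LOC400236, SDC3, USP53, MTX3, CBLN3 and ARHGAP5. A lower slope need not be faster loss. LOC400236, SDC3 and ARHGAP5 had slopes of 0.472, 0.626 and 0.472 in the control, a rise relative to the median gene. In the long-labelled series they had -0.365, -0.117 and 0. Of 27 called slope differences of named genes, 25 lost the call when at least 1 of the times was left out, 23 of them without the 6 h libraries. Those of CITED4 and RHOB did not. The count was 0 when only the 12 libraries compared were fitted. It was 7 without the 6 h libraries, 18 without those of 0.5 h, 56 without 0 h, 54 without 1 h and 64 without 2 h. Leaving out the long-labelled library of 6 h gave 26, that of 0 h 77, of 0.5 h 88 and of 1 h 94. Without the control library of 6 h it was 50, and without that of 0.5 h 81.

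In the short-labelled series, 12 of 102 zinc-finger mRNAs were lost more slowly than in the control. The mRNA of HSPA5, the chaperone BiP of the endoplasmic reticulum, fell there while it rose unevenly in the control. The list had 12 higher and 0 lower slopes (adjusted over the list alone, 13 and 0; camera adjusted p = 0.023, and adjusted p = 0.0277 with an estimated correlation). Without centring the FPKM the call was lost (adjusted p = 0.0792). ZNF330 (0.24 ± 0.03), ZNF622 (0.19 ± 0.03), ZNF317 (0.25 ± 0.04) and ZNF828 (0.69 ± 0.14) had the smallest p-values. HSPA5 had a slope of 0.30 in the control and -0.48 in the short-labelled series, a difference of -0.78 ± 0.16 (limma adjusted p = 0.00637). That call was lost without the libraries of 0 h (adjusted p = 0.0505) or 6 h (0.238). In time order its control values were 122.92, 261.73, 263.06, 106.63, 417.41 and 421.49 FPKM. The short-labelled values were 111.25, 65.98, 28.4, 66.7, 22.74 and 8.07. Part of the difference is thus the uneven rise in the control.

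Over all genes, 696 slopes differed between the short-labelled and control series, 331 higher and 365 lower. Besides ZNF828, the 10 largest higher slopes were those of GPATCH8 (0.63 ± 0.14), the vesicle transport gene BET1 (0.60 ± 0.15), TTC5, URB2, SURF6 (0.53 ± 0.07), KIAA0907 (0.50 ± 0.07), the N-terminal acetyltransferase subunit gene NAA25 (0.45 ± 0.09), HHEX (0.45 ± 0.10) and C7orf25 (0.44 ± 0.08). The largest lower slopes were those of the vesicle fusion gene VAMP7 (-0.86 ± 0.21), SDC3 (-0.82 ± 0.16), SNX19 (-0.79 ± 0.15), HSPA5, the transporter gene CNNM2 (-0.66 ± 0.18), the septin gene SEPT8 (-0.66 ± 0.09), TBC1D9, RIF1, the G protein gene GNA12 (-0.61 ± 0.11) and the polarity gene PARD3. Of 29 called slope differences of named genes, 21 lost the call when at least 1 of the times was left out, 19 of them without the 6 h libraries. The count was 54 when only the 12 libraries compared were fitted. It was 280 without the 6 h libraries, 442 without those of 0.5 h, 354 without the control library of 6 h and 333 without the short-labelled library of 6 h.

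The both-labelled series shared the lower slope of HSPA5, with a difference of -0.88 ± 0.16 from the same uneven control course (limma adjusted p = 0.00397, and 0.17 without the 6 h libraries). Of the zinc-finger genes 8 of 102 had a higher and 1 a lower slope against the same control libraries (adjusted over the list alone, 8 and 1; camera adjusted p = 0.0228, and adjusted p = 0.0275 with an estimated correlation), among them ZNF622 (0.22 ± 0.03), ZNF317 (0.23 ± 0.04), ZNF330 (0.16 ± 0.03) and ZNF7 (0.24 ± 0.06). Without centring the FPKM that list call was lost (adjusted p = 0.0931). CITED4 (0.50 ± 0.04), SURF6 (0.50 ± 0.07), ZNF828 (0.51 ± 0.14) and HHEX (0.49 ± 0.10) were lost more slowly than in the control in this series too. The same control libraries serve the long-labelled, short-labelled and both-labelled comparisons, so these are not separate findings. For ZNF828 the control slope was -1.07, against -0.455, -0.378 and -0.56 in those series. It was -0.814 against -0.28, -0.364 and -0.322 for HHEX. The control also stood apart for SURF6 (-0.624 against -0.18, -0.1 and -0.127) and CITED4 (-0.716 against -0.285, -0.366 and -0.212). In all, 554 slopes differed, 301 higher and 253 lower; without centring the FPKM, the split was 424 and 190. Other higher slopes among the 10 largest were those of the actin nucleation gene WHAMM (0.68 ± 0.17), FBXO42 (0.65 ± 0.08), ELP4 (0.48 ± 0.11), ZNF337, LOC100630923 and LOC100129361. The lower ones, besides HSPA5, were the phosphatase gene PPM1A (-0.79 ± 0.16), the chromatin remodeller gene SMARCAD1 (-0.73 ± 0.14), SDC3, CNNM2, ZFP36L2 (-0.64 ± 0.14), which encodes a protein that promotes decay of AU-rich mRNAs, PHF3, C12orf59, the ubiquitin ligase gene MARCH8 (-0.51 ± 0.09) and ZNF703. Of 29 called slope differences of named genes, 22 lost the call when at least 1 of the times was left out, 19 of them without the 6 h libraries. The count was 54 when only the 12 libraries compared were fitted, 181 without the 6 h libraries, 330 without 0 h and 304 without 0.5 h. Without genes whose 3' UTR holds any of 4 heptamers, hence with fewer genes tested, it was 363. It was 228 without the control library of 6 h and 192 without the both-labelled library of 6 h.

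**Figure D2:**
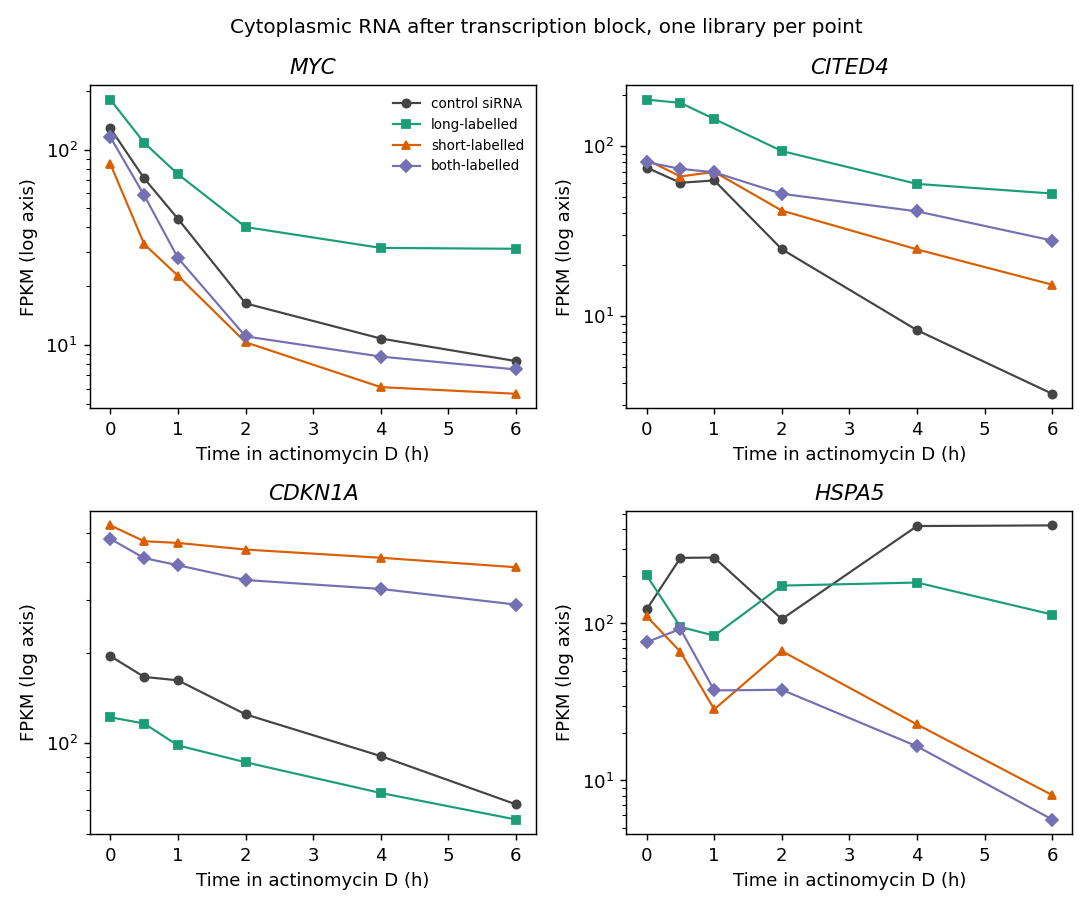
FPKM on a log axis against hours in actinomycin D for MYC, CITED4, CDKN1A and HSPA5, 1 point per library and 1 line per series. MYC in the long-labelled series ends at 31.1 FPKM against 8.29 in the control, CITED4 declines least steeply in the both-labelled and long-labelled series, and HSPA5 declines in the short-labelled and both-labelled series.

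The short-labelled and long-labelled series were also compared with each other. Of the immediate-early genes 12 of 47 had a lower and 0 a higher slope in the short-labelled series (adjusted over the list alone, 15 and 2), with RHOB at -0.19 ± 0.03, KLF10 at -0.45 ± 0.06, CYR61 at -0.28 ± 0.04 and ID3 at -0.24 ± 0.05. The list passed camera (adjusted p = 0.000953) but not with an estimated correlation (adjusted p = 0.325). The zinc-finger list did not pass here (camera adjusted p = 0.437). EXOSC4 (0.61 ± 0.07) and PKMYT1 (0.49 ± 0.09) had higher slopes in the short-labelled series, as did the replication gene POLA2 (0.51 ± 0.13), RBM28 (0.46 ± 0.10), TM9SF3 (0.54 ± 0.12), RBAK, NAIF1, CBLN3, ZBTB24 and LOC100133161. SNX19 (-0.86 ± 0.15), VAMP7 (-0.85 ± 0.21), the mitochondrial enzyme gene IDH2 (-0.75 ± 0.21), the cell-cycle inhibitor gene CDK2AP1 (-0.67 ± 0.09), SEPT8 (-0.66 ± 0.09), TBC1D9, MED7, PCDH1, ZFP36L2 and GNA12 had lower slopes. These differences need not be slower or faster loss. IDH2 and CDK2AP1 had slopes of 0.393 and 0.239 in the long-labelled series, a rise relative to the median gene. In the short-labelled series RBAK and PKMYT1 had 0.394 and 0.196. With limma 495 slopes differed, 175 higher and 320 lower in the short-labelled series. Of 29 called slope differences of named genes, 23 lost the call when at least 1 of the times was left out, 19 of them without the 6 h libraries. The count was 92 when only the 12 libraries compared were fitted, 160 without the 6 h libraries, 297 without 0 h, 245 without 0.5 h, 196 without the long-labelled library of 6 h and 231 without the short-labelled library of 6 h.

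Whether the both-labelled series departed from the sum of the long-labelled and short-labelled differences was tested as an interaction. No gene passed: limma called 0 of 7860, with 742 at an unadjusted p under 0.05, and leaving out the control library of 4 h gave 10. The heat shock gene HSPA8 (-0.16 ± 0.02, limma adjusted p = 0.0566) came closest, followed by CDKN1A (-0.12 ± 0.02), RAD1, TBC1D10A and CITED4 (-0.28 ± 0.05) below 0 and MTX3 (0.55 ± 0.10), LHFPL2, B4GALT2, ARHGAP5 and TSPAN6 above 0. Immediate-early genes passed as a list (camera adjusted p = 0.00176, median -0.071), with 0 members past the threshold over all genes and, adjusted over the list alone, 1 above and 4 below 0. The call was lost with an estimated correlation (adjusted p = 0.195). RHOB stood at -0.15 ± 0.04 and BTG2 at -0.30 ± 0.07.

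The slope changes of the series were compared across genes, which are not independent replicates. Between the long-labelled and short-labelled series the correlation was 0.474, against 0.5 for simulated unchanged series that share the control libraries, and the covariance exceeded the simulated value by 0.0021. With the control libraries split between the 2 comparisons the correlation was 0.065 or 0.082. Control slopes then rest on 0, 1 and 4 h or on 0.5, 2 and 6 h, and the other slopes on all times. That adds scatter, so low values with split controls do not show that a shared effect is absent. For the long-labelled and both-labelled series the values were 0.532, 0.502 and 0.00253, and 0.097 or 0.105 with split controls. The short-labelled and both-labelled series reached 0.675 against 0.503, with a covariance difference of 0.00602 and split-control values of 0.25 and 0.237. They shared 214 higher and 174 lower calls, where independent lists would share 12.7 and 11.7, and 0 genes were called in opposite directions. The long-labelled series shared 62 higher and 11 lower calls with the short-labelled series (4.1 and 2.1 for independent lists) and 66 and 17 with the both-labelled series (3.8 and 1.5), with 2 genes called in opposite directions in each. The shared control libraries also add shared calls, by an amount not estimated here, so the counts for independent lists are not those of no shared effect.

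The spread of slopes over the transcriptome, taken as their interquartile range, was 0.1765 log2 units per h in the control, 0.1521 in the long-labelled, 0.1769 in the short-labelled and 0.1642 in the both-labelled series. The ratio to the control was 0.8615 in the long-labelled series (exact permutation of the series within times, p = 0.125) and 1.0021 in the short-labelled series (exact p = 0.969). In the both-labelled series it was 0.9304 (exact p = 0.031, the smallest that the 32 swaps allow). That call was lost under most other settings, and without the both-labelled library of 6 h the ratio was 1.1467. The short-labelled against the long-labelled series gave 1.1632 (exact p = 0.188).

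RNA levels, averaged over the 6 times, differed between the series far more often than slopes did. In the long-labelled series cholesterol synthesis genes were lower. Of these, 18 of 24 fell and 2 rose (adjusted over the list alone, 19 and 2; camera adjusted p = 4.08e-05, and adjusted p = 0.00178 with an estimated correlation). FDFT1, the squalene synthase gene, fell by 1.04 on the log2 scale (SE 0.07), SC4MOL by 0.70 (SE 0.05) and HMGCS1 by 0.48 (SE 0.04). Interferon response genes had 14 of 22 members lower and 5 higher (adjusted over the list alone, 14 and 5; camera adjusted p = 0.00881, and adjusted p = 0.0752 with an estimated correlation), with ISG15 at -1.92 ± 0.07, OASL at -2.12 ± 0.09 and IFIT2 at -1.41 ± 0.08. S phase genes had 16 of 36 members higher and 0 lower (adjusted over the list alone, 16 and 0; camera adjusted p = 0.0111, and adjusted p = 0.0573 with an estimated correlation), with the replication helicase genes MCM3 at 0.80 ± 0.03 and MCM6 at 1.06 ± 0.17, ORC1 at 0.59 ± 0.07 and TYMS at 0.45 ± 0.05.

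Over all genes, 4023 levels differed between the long-labelled and control series (limma), 2128 higher and 1895 lower, of which 375 and 371 by 2-fold or more on the log2(FPKM + 0.1) scale, which understates changes of low genes. HMOX1 stood at 110.52 FPKM against 7.46, 19.5-fold higher on that scale. The p53 target PMAIP1 was 6.69-fold higher (22.03 against 3.44 FPKM), although of the 25 p53 targets 5 were higher and 11 lower (adjusted over the list alone, 5 and 11; camera adjusted p = 0.142). Also higher were RECK, C9orf41, HIST1H4C, POLR3G, TIGD1, LCLAT1 and CEP135, by 5.48-fold to 7.78-fold. The vitamin A transporter gene STRA6 was 17.5-fold lower (1.14 against 21.57 FPKM), and A2M, OLFML2A, SCARA5, LRG1, the growth factor receptor gene FGFR3, the sialyltransferase gene ST6GAL1 and the xenobiotic-metabolising gene CYP1A1 were 8.19-fold to 15.8-fold lower. NME7 was listed at 0 throughout the control series and at a mean of 12.35 FPKM here. TTC7A and C18orf8, at 10.44 and 8.94 FPKM in the control, were listed at 0 in all 6 long-labelled libraries. Zeros throughout a series, here and in the comparisons below, can be failed estimates that the rule for zeros does not catch.

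In the short-labelled series p53 target genes were higher and genes of the G2 and M phases lower than in the control. Of 25 p53 targets 21 rose and 2 fell (adjusted over the list alone, 22 and 2; camera adjusted p = 5.88e-06, and adjusted p = 0.0113 with an estimated correlation). SESN1 rose by 2.15 ± 0.05, PMAIP1 by 2.67 ± 0.09 and the CDK inhibitor gene CDKN1A by 1.93 ± 0.11, from 133.43 to 450.07 FPKM, whereas GDF15 fell by 2.22 (SE 0.14). G2 and M phase genes fell in 21 of 31 cases and rose in 3 (adjusted over the list alone, 21 and 3; camera adjusted p = 0.00063, and adjusted p = 0.0113 with an estimated correlation), with TOP2A at -1.23 ± 0.05, BUB1 at -1.23 ± 0.06, BIRC5 at -0.82 ± 0.05 and the centromere histone gene CENPA at -2.72 ± 0.17. Ribosomal protein genes had 33 of 64 members lower and 2 higher (adjusted over the list alone, 33 and 2; camera adjusted p = 0.000237, and adjusted p = 0.25 with an estimated correlation), among them RPL31 (-1.17 ± 0.05) and RPS25 (-0.90 ± 0.05). Interferon response genes had 14 of 22 members higher and 4 lower (adjusted over the list alone, 14 and 4; camera adjusted p = 0.0238, and adjusted p = 0.18 with an estimated correlation), with IFIT2 at 1.43 ± 0.08 and IFIH1 at 1.14 ± 0.10. Extracellular matrix genes had 10 of 18 members higher and 1 lower (adjusted over the list alone, 10 and 1). Camera gave them an adjusted p = 0.0392, and an adjusted p = 0.222 with an estimated correlation. TGFBI (2.32 ± 0.05) was among those higher, and THBS1 (-1.49 ± 0.11) was the member that fell. Glycolysis genes had 8 of 13 members lower and 1 higher (adjusted over the list alone, 8 and 1; camera adjusted p = 0.0471, and adjusted p = 0.236 with an estimated correlation), including ALDOC (-2.78 ± 0.11), PFKP (-1.01 ± 0.05) and GAPDH (-1.21 ± 0.12).

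In all, 4988 levels differed between the short-labelled and control series, 2572 higher and 2416 lower (limma), of which 735 and 784 by 2-fold or more. The lipase inhibitor gene ANGPTL4 was 11.6-fold higher (15.23 against 1.34 FPKM), the matrix gene TNC 11.2-fold, RECK 11-fold and TBC1D2 11.6-fold. KLRC2 and FAM26D rose from 0.23 and 0.16 to 3.66 and 2.92 FPKM. CDK2AP1 went from 89.39 to 4.37 FPKM, 23.6-fold lower, PPDPF from 138.23 to 3.03 and the endoplasmic reticulum chaperone gene HSPA5 from 265.54 to 50.52. These means hide the course of HSPA5, which at 0 h stood at 122.92 FPKM in the control and 111.25 in the short-labelled series. SLC45A4, TRAPPC6A, SLC25A43, the smooth muscle actin gene ACTG2 and the placental phosphatase gene ALPP, which has a close paralogue that may share its reads, were 16.3-fold to 31.1-fold lower. S100PBP, TMOD1, CCDC24 and KMO were listed at 0 in the control series and at means of 9.86, 7.34, 3.63 and 7.01 FPKM here. DHPS, the deoxyhypusine synthase gene, C18orf8 and APIP were at 48.52, 8.94 and 6.83 FPKM in the control and listed at 0 in all 6 short-labelled libraries. These zeros too can be failed estimates.

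The both-labelled series resembled the short-labelled series in its levels. p53 targets rose in 22 of 25 cases and fell in 1 (adjusted over the list alone, 22 and 1; camera adjusted p = 1.07e-05, and adjusted p = 0.0196 with an estimated correlation), with SESN1 at 2.18 ± 0.05, AEN at 1.04 ± 0.06 and CDKN1A at 1.64 ± 0.11. G2 and M phase genes fell in 19 of 31 cases and rose in 4 (adjusted over the list alone, 19 and 5; camera adjusted p = 0.00679, and adjusted p = 0.0416 with an estimated correlation), with BUB1 at -1.03 ± 0.06, CENPA at -2.25 ± 0.17 and TOP2A at -0.63 ± 0.05. Ribosomal protein genes had 35 of 64 members lower and 2 higher (adjusted over the list alone, 35 and 2; camera adjusted p = 0.000112, and adjusted p = 0.295 with an estimated correlation), among them RPL14 (-0.78 ± 0.06). In all, 4878 levels differed, 2597 higher and 2281 lower, of which 695 and 672 by 2-fold or more. ANGPTL4 stood at 19.35 FPKM, TNC at 9.72, the lipase gene LIPH at 13.93 against 1.58 in the control and TBC1D2 at 27.25. KLRC2 and FAM26D were 9.95-fold and 9.80-fold higher. CDK2AP1 stood at 3.92 FPKM, PPDPF at 4.89, HSPA5 at 44.3 and CYP1A1 at 1.52 against 26.79 in the control. ACTG2, ALPP, SCARA5 and MPND were 13.2-fold to 20.9-fold lower. S100PBP, TMOD1, CCDC24 and KMO were again listed at 0 only in the control among these 2 series, and DHPS, C18orf8 and APIP only in the both-labelled series.

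**Figure D3:**
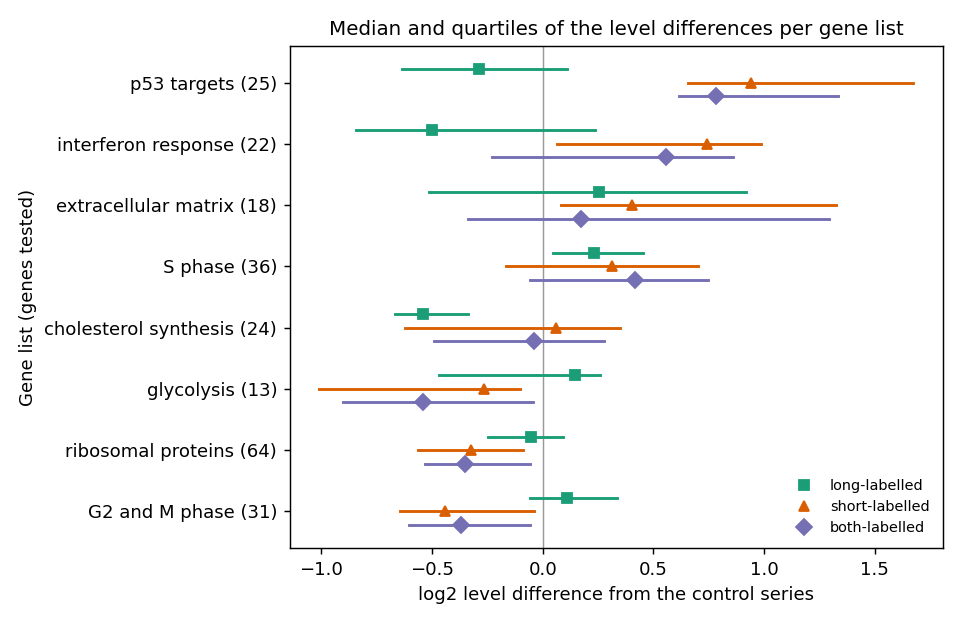
Median (symbol) and quartiles (bar) of the log2 level difference from the control series for the genes of 8 lists, by series, with the number of genes tested in brackets. p53 targets lie above 0 in the short-labelled and both-labelled series, with medians of 0.939 and 0.782, and cholesterol synthesis genes lie at -0.542 in the long-labelled series.

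Set directly against the long-labelled series, the short-labelled series had higher p53 targets. There were 22 of 25 higher and 0 lower (adjusted over the list alone, 22 and 0; camera adjusted p = 1.41e-07, and adjusted p = 0.00276 with an estimated correlation), with SESN1 at 1.97 ± 0.05, TP53I3 at 1.79 ± 0.06 and CDKN1A at 2.39 ± 0.11. Interferon response genes were higher in 17 of 22 cases and lower in 2 (adjusted over the list alone, 17 and 3; camera adjusted p = 5.46e-05, and adjusted p = 0.0101 with an estimated correlation), with ISG15 at 2.69 ± 0.07 and OASL at 2.46 ± 0.09. Cholesterol synthesis genes were higher in 14 of 24 cases and lower in 4 (adjusted over the list alone, 14 and 4; camera adjusted p = 0.0174, and adjusted p = 0.031 with an estimated correlation), with SC4MOL at 1.33 ± 0.05 and FDPS at 0.83 ± 0.06. G2 and M phase genes were lower in 25 of 31 cases and higher in 2 (adjusted over the list alone, 25 and 2; camera adjusted p = 1.17e-05, and adjusted p = 0.00276 with an estimated correlation), with TOP2A at -1.45 ± 0.05 and CKS2 at -0.98 ± 0.04. Ribosomal protein genes were lower in 27 of 64 cases and higher in 7 (adjusted over the list alone, 26 and 5; camera adjusted p = 0.0174, and adjusted p = 0.466 with an estimated correlation). In all, 5027 levels differed, 2488 higher and 2539 lower in the short-labelled series (limma), of which 672 and 746 by 2-fold or more. AGR2, a secretory pathway disulfide isomerase gene, stood at 29.92 FPKM against 0.6, the epithelial transcription factor gene SPDEF at 2.19 against 0.05, and the junction gene F11R and CLCA2 were 12.2-fold and 11.6-fold higher. HMOX1 was 30.2-fold lower, and EBAG9, TRIM16L, SLC45A4, TRAPPC6A, CDK2AP1 and PPDPF were 13.3-fold to 45.6-fold lower.

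Level differences were also set beside each other across genes. The short-labelled and both-labelled series correlated at 0.93, against 0.505 for simulated unchanged series, with a covariance difference of 0.633, and at 0.857 or 0.866 with split controls. They shared 2204 higher and 1949 lower calls (849.8 and 701.1 for independent lists), and 36 genes were called in opposite directions. The long-labelled series correlated at 0.384 with the short-labelled series, against 0.5 for simulated unchanged series (0.317 or 0.325 with split controls). They shared 1183 higher and 904 lower calls (696.3 and 582.5 for independent lists), and 834 genes were called in opposite directions. With the both-labelled series the correlation was 0.538, against 0.499 (0.458 or 0.474 with split controls). They shared 1357 higher and 1044 lower calls (703.1 and 549.9 for independent lists), with 580 in opposite directions. The covariance exceeded the simulated one by 0.189 and 0.264. Shared control libraries add to the shared calls of levels too. Values with split controls rest on fewer control times here as well.

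Lists closest to the function of PAN3 did not pass in any of the 10 comparisons of slopes and levels. The smallest adjusted p of camera was 0.156 for 36 genes of the mRNA decay machinery, 0.117 for 7 genes of the microRNA machinery, 0.142 for 17 targets of the let-7 microRNA and 0.117 for 22 targets of nonsense-mediated decay. It was 0.197 for 10 replication-dependent histone genes, 0.212 for 4 nuclear-retained RNAs and 0.243 for 29 genes of the unfolded protein response. Members of these lists passed singly. In the short-labelled series the levels of 6 of 36 mRNA decay genes rose and those of 14 fell (adjusted over the list alone, 5 and 13), and of 22 targets of nonsense-mediated decay 4 rose and 10 fell (adjusted over the list alone, 4 and 10). Over all genes 63.5% of levels were called in that comparison, so these counts do not set the lists apart. Of 20 markers of other cell types, 2 were abundant enough to be tested, and 0 genes encoded by the mitochondrial genome were in the table.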

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

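The test of a floor, the comparison with uncentred FPKM and the swaps of libraries were chosen after the results had been seen, as was the comparison of the zinc-finger shift between series. The bound for a later block of transcription was fixed before its own result. The following lists stood out because a test of the difference itself separated the short-labelled from the long-labelled series, or the both-labelled series from the sum of the other differences. By level, p53 targets (camera adjusted p = 1.41e-07, median difference 1.157), interferon response genes (5.46e-05, 0.862) and cholesterol synthesis genes (0.0174, 0.375) were higher in the short-labelled than in the long-labelled series. G2 and M phase genes (1.17e-05, -0.525) and ribosomal protein genes (0.0174, -0.21) were lower, and for the ribosomal proteins the call was lost with an estimated correlation (adjusted p = 0.466). By slope, the immediate-early list lay lower in the short-labelled than in the long-labelled series (0.000953, -0.052), and their both-labelled slopes lay below the sum of the other changes (0.00176, -0.071). Both slope calls were lost with an estimated correlation (adjusted p = 0.325 and 0.195).

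The higher slopes of the immediate-early list in the long-labelled series were weighed further. The median slope difference of the 47 genes was 0.191 over 0 to 2 h (35 above 0) and 0.028 over 2 to 6 h. Over 0 to 6 h it was 0.075 with centring and 0.083 in FPKM as deposited, so centring did not create it. The median of all genes was 0.004 as deposited. Scaling a library moves all genes alike and cannot set the list apart from them, so these values are no test of it. A later block of transcription in that series stays open: the 102 zinc-finger genes, also short-lived, had a median difference of 0.087 over 0 to 2 h (quartiles -0.087 and 0.348), where such a block would give 0.064, but they had 0.1 in the short-labelled and 0.079 in the both-labelled series, where the immediate-early genes had 0.01 and 0.07. A higher floor of residual RNA stays open too, since the list was nearly flat from 2 to 6 h in the long-labelled series (median slope -0.068, after -0.828 over 0 to 2 h) and in the control (-0.063, after -1.083), as does slower decay with loss of the long isoform.

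Libraries were also exchanged between the series compared at every subset of the 6 times, in 32 distinct swaps. For slopes, 2 of 32 gave as many calls as the real series in each of the 4 comparisons. The other was the swap of the 2 h libraries alone, which leaves 99.5% of a slope difference in place, so these swaps are too few for a share under 0.05. The real counts were 144, 696, 554 and 495 for the long-labelled, short-labelled, both-labelled and short-against-long comparisons, and the highest others 147, 767, 602 and 541, or 27, 402, 192 and 257 apart from that swap. For the departure from the sum, with 0 calls by limma (742 at an unadjusted p under 0.05), all 32 swaps had to give at least as many, so they say nothing about chance; the highest was 5. For levels, 1 of 32, the real series, gave as many calls, with 4023, 4988, 4878 and 5027 calls against at most 1823, 3169, 2913 and 2993. That is the smallest share these swaps can give. Any shift common to the libraries of a series would give it too, so chance differences between transfections are not excluded. The swaps do not separate an siRNA from the transfection that carried it.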

How the results depend on the processing

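The alternatives with zeros kept, genes with any 0 left out, transcripts in place of genes, genes with certain heptamers left out, and 0 to 2 h were chosen after seeing the data. Where no cause is given, the cause was not tested. Over shorter time ranges, and with only the libraries compared, fewer slopes were called in the long-labelled, short-labelled, both-labelled and short-against-long comparisons (144, 696, 554 and 495): 7, 280, 181 and 160 over 0 to 4 h, 0, 4, 2 and 0 over 0 to 2 h, and 0, 54, 54 and 92 with only the 12 libraries compared. A straight line for each series gave 54, 346 and 297 in the long-labelled, both-labelled and short-against-long comparisons, and no filter gave 64 in the long-labelled and 328 in the short-against-long comparison. Leaving out genes with a heptamer gave 363 in the both-labelled series. That setting tests fewer genes and the share called is not given, so the lower count alone does not show an effect of the heptamers. Leave-one-out counts ran from 7 to 152, 280 to 701, 181 to 528 and 160 to 465, with 7, 280, 181 and 160 without the 6 h libraries. The 0 calls of the departure from the sum (limma; 742 at an unadjusted p under 0.05) became 12 at 5 FPKM or more, 2 with quantile normalization, with transcripts and over 0 to 4 h, 1 uncentred, without heptamer genes and over 0 to 2 h, and 0 to 10 in leave-one-out. Without a filter, which tests more genes, 7949 levels differed in the short-labelled series, 7861 between short-labelled and long-labelled, and 8265 slopes in the control; over 0 to 2 h the control count was 1107.

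The ratio of slope spread in the both-labelled series (0.9304) lost its call at 0.9303 with a pseudocount of 1, 0.9336 with 0.01, 0.9384 and 0.9224 with filters of 0.1 and 5 FPKM, 0.9355 without a filter, 0.9035 with quantile normalization, 0.9367 with zeros kept, 0.923 with transcripts and 0.9144 without heptamer genes. It ran from 0.7698 to 1.1467 in leave-one-out, reversed without the both-labelled library of 6 h. A call was gained in the long-labelled series with quantile normalization (0.8493) and between short-labelled and long-labelled without a filter (1.1087). The correlation of slope changes (0.474) was 0.46 with a pseudocount of 0.01, 0.492 with zeros kept, 0.483 without genes holding a 0, 0.444 by Spearman, and 0.473 to 0.482 in leave-one-out. Of the 28 list calls 11 held with an estimated correlation, and fry, which does not compare a list with other genes, made 85. Of 346 differences of named genes 331 kept their side of the threshold with a pseudocount of 1 and 265 without the 6 h libraries, and 0 reversed in the settings run. Read depth is unknown, so no limit from depth can be given.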

Other observations

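Other than the test of the unfolded protein list, the tests here were chosen after the data had been seen, as were the genes and heptamers named. In the short-labelled and both-labelled series HSPA5, the major chaperone of the endoplasmic reticulum, was lower in its mean over the 6 times, while some other genes of the unfolded protein response were higher and some lower. HSPA5 differed from the control by -2.56 log2 units in the short-labelled series (limma adjusted p = 0.00135) and by -2.82 in the both-labelled series (limma adjusted p = 0.000615). At 0 h it stood at 122.92 FPKM in the control, 111.25 in the short-labelled and 76.06 in the both-labelled series. At 6 h the values were 421.49, 8.07 and 5.64, so much of the difference opened during the treatment. CRELD2 was higher by 1.87 and 1.81, DNAJC3 by 1.67 and 1.6, SDF2L1 by 1.55 and 1.6, PDIA4 by 1.25 and 1.15, CALR by 1.21 and 1.07 and the transcription factor gene XBP1 by 1.02 and 1.08. These 7 genes passed limma in both series, also with any 1 of the times left out. As a list the unfolded protein response did not pass: in the short-labelled series 13 of 29 genes were higher and 11 lower (adjusted over the list alone, 13 and 11; camera adjusted p = 0.413), and in the both-labelled series 13 and 10 (adjusted over the list alone, 14 and 10; camera adjusted p = 0.243). The 6 genes named as higher were chosen from these after their values had been seen.

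Genes whose 3' UTR holds the heptamer GACACCA were lower in the short-labelled and both-labelled series. The 626 genes with it differed from other genes by -0.50 log2 units in the short-labelled series. The t was -14.1, the lowest of 14591 heptamers, where the largest absolute t of 100 shuffles was 5.16. In the both-labelled series the t was -13.71 (shuffles 5.06) and in the long-labelled series -2.54 (shuffles 5.4). At single times the difference ran from -0.576 to -0.407 in the short-labelled and from -0.532 to -0.38 in the both-labelled series, and from -0.113 to -0.041 in the long-labelled series; the heptamer was chosen on the mean of these times, so the signs at single times are no separate test. Among the named genes with a 3' UTR, 5 of 9 with a lower level in the short-labelled series hold the heptamer. In the both-labelled series 3 of 9 do, and 2 of 10 with a lower slope in the short-labelled series. HSPA5, CDK2AP1, PPDPF, SLC25A43, SLC45A4 and ALPP hold it, whereas DHPS, APIP, ACTG2 and TRAPPC6A do not. DHPS and APIP were listed at 0 throughout the short-labelled series, which can be a failed estimate. The heptamer was held by 287 of the 2138 genes with a 3' UTR that were lower in the short-labelled series (13.4%, against 7.0% of other genes). It was held by 68 of the 327 with a lower slope there (20.8%, against 8.4%). In the long-labelled series the lowest heptamer was ACAGGTG, in 1124 genes, with a t of -7.78, against 0.35 in the short-labelled and -2.59 in the both-labelled series. GAATATA was the highest heptamer in the long-labelled, short-labelled and both-labelled series, with t of 12.81, 10.46 and 10.34. These 3 comparisons share the 6 control libraries and are not separate findings. Between the short-labelled and long-labelled series, without the control, its t was 0.98, and no explanation of it was tested.

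For the lower levels of genes with GACACCA, a trend of 3' UTR length or GC content is argued against as the whole cause, since both were in the regression that gave -14.1. A candidate explanation is pairing of the siRNA seeds with these 3' UTRs, as microRNAs pair; the siRNA sequences are not given in the sources used here. In GRCh38 with GENCODE release 29, ACAGGTG lies in PAN3 on chromosome 13 at 28197279 to 28197285, inside exon 5 (28197185 to 28197346) of a transcript of 2833 bases, an exon that the transcript of 4940 bases lacks. These lengths do not tell which is the long isoform. The transcript of 2833 bases has the additional exon 5 of 162 bases. The other has a last exon of 2954 bases, against 158. GACACCA occurs once in each transcript, with 1 base before and 6 after the junction into the exon that holds 28220231 to 28220236, so the heptamer alone does not separate the transcripts. The bases before it lie in exon 5 of the transcript of 2833 bases and in exon 4 of the other. A longer site that ends in GACACCA could therefore separate them. Of the heptamers, 1.12% touch exon 5 or its junctions, as both leading ones do. The junction that skips exon 5 in the transcript of 4940 bases is touched by 0.04%, GACACCA among them and ACAGGTG not. CAGGTGA, next lowest in the long-labelled series with a t of -7.23, has its PAN3 sites in other exons. It overlaps ACAGGTG in all but 1 base, so the heptamers are not separate, and whether its sites bear on seed pairing was not tested. Loss of the short isoform acting through GACACCA cannot be told apart from seed pairing, because both need the shift in each library with that siRNA, and it was missing in 0 of 12.

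No test found PAN3 lower in the libraries labelled as knockdowns. Single mislabelled libraries are argued against, as 24 of 24 libraries were nearest to their own series once the mean of each time was removed; a whole series under a wrong label was not tested by this. An unreliable FPKM of this transcript stays open, since the scatter of PAN3 within the control series, an SD of 1.63 log2 units, lay at the 81.1 percentile of 1069 genes with a mean of 1 to 2 FPKM (median 0.635); without the control library of 6 h, listed at 0, the SD was 0.897, at the 86.9 percentile of 817 genes with no 0 at the other times (median 0.454). A rise of the isoform that was not targeted was not tested, as the table holds a single PAN3 transcript.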
